A study of Homo sapiens with 44 samples.

How the data were processed

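RNA was measured by sequencing of polyadenylated transcripts in 44 libraries of 3 human prostate cancer cell lines. Per the labels, libraries were run on a HiSeq 2000 instrument with reads of 100 nt. The deposited values are TPM, a length-normalised share of each transcript, for 188753 transcripts in each library, normalised by the authors for transcript length and library size, so that each library sums to 1000000. Per the submitters' processing notes, STAR 2.4.1, featureCounts, edgeR and the GRCh38 genome build were used in the series, with no statement of which step each served. The tool that made the TPM values, and its annotation, are not given in the sources used here. TPM keep no record of read number, so the sequencing depth of each library is unknown, and neither counting intervals nor limits on values of 0 can be given.

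Transcript TPM were summed to genes with the GENCODE 29 annotation of GRCh38, matching transcript identifiers without their version. Of the 188753 transcripts, 169797 (90.0%) matched, giving 35579 genes, and 18956 did not. Unmatched transcripts held between 2.79% and 6.04% of a library's TPM and were left out. Gene values were divided by a library factor, because a few abundant classes of transcript took different shares of the libraries. It came from an unweighted trimmed mean of log ratios (30% of ratios and 5% of mean levels trimmed at each end). This scaling takes the bulk of genes as unchanged, and TPM are shares. A rise or fall of all transcripts alike therefore cannot be seen, and changes are relative to that bulk. Genes were kept with at least 1 TPM in at least 2 VCaP libraries, or at least 3 libraries of the Du145 ZBC-260 set, which left 15265 and 15698 genes.

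Groups were taken from the sample titles and treatment tags. VCaP and Du145 titles that read ZBX-246 were taken as ZBC-246, the name in the 22Rv1 titles, and VCaP results for that degrader rest on this reading. The 16 VCaP libraries formed 8 groups of 2, made of 4 treatments at 2 times. The 12 Du145 libraries of the ZBC-260 set formed 4 groups of 3. Their controls are titled as DMSO while their treatment tag reads thalidomide, and they are called controls here. Du145 and 22Rv1 libraries treated with DMSO, thalidomide, ZBC-246 or ZBC-11 had 1 library per group. The series' design text also names a compound that no sample label carries, which was not analysed here. Nothing in the labels says that replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

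Count data had been assumed when the tests were fixed. With TPM, log2(TPM + 1) values were fitted with limma 3.58.1 in R 4.3.3, with a variance trend and moderated spread, in 1 fit of all groups per set and 8 residual degrees of freedom. Contrasts were two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Every adjusted p for a gene comes from that limma test, and every log2 fold change is on the log2(TPM + 1) scale, which understates changes of genes with low values. The estimated difference between 24 h and 3 h effects was tested as an interaction. The effect of a single VCaP fit for both times is that the spread is shared: the median SD between replicates was 0.201 on the log2 scale at 3 h and 0.472 at 24 h, and both take in any shift shared by libraries of the same replicate number, which this fit does not separate. A fit on libraries of the same time only was added after the data were seen, and it too counts such a shift as spread between replicates.

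Before the data were examined, 38 gene lists were fixed from general knowledge. Each was tested within a comparison by camera, with a preset correlation between genes of 0.01 and again with an estimated correlation, adjusted over the lists. Lists with under 3 tested members were not tested. Members that passed are counted over all genes tested and adjusted over the list alone. A list set aside here as markers of the response to BET inhibitors came from other studies, not from these samples. For 13 of the 38 lists no comparison passed. The rule for named genes was also fixed beforehand. Among genes with adjusted p below 0.05, mean TPM of at least 5 and no overlap between groups, it takes the 8 largest rises and 8 largest falls per comparison (4 and 4 between compounds) and up to 4 members of each list with the smallest p. MYC, HEXIM1, BRD2, BRD3, KLK3, TMPRSS2, ERG, FKBP5, SERPINI1, BCL2, BCL2L1, CDKN1A and FOSL1 were always taken. Results for some genes are not reported here. The rule takes the largest changes, so their sizes are overestimates on average.

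For single libraries, log2 ratios were computed with no test, and a list's median was placed among 10000 random lists of the same size matched on mean expression. Correlations between comparisons are across genes, which are not independent replicates. Where 2 comparisons shared control libraries, 100 simulations of unchanged groups gave the value that sharing alone sets, with noise independent between libraries.

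The procedure was tested on simulated data built from the real genes, with 100 genes changed by log2 1 and 100 by log2 2. For ZBC-246 at 3 h in VCaP, 0 of the smaller and 58 of the larger changes were recovered, with 3 false calls. For ZBC-246 at 24 h, 19 and 74 were recovered with 94 false calls, and for ZBC-11 at 24 h 18 and 73 with 134 false calls. On libraries of the same time only, 71 and 99 were recovered for ZBC-246 at 3 h with 12 false calls, while at 24 h 0 and 1 were recovered with 1 false call. The simulated noise was independent between libraries, so it lacked any shift shared by VCaP libraries of the same replicate number. Recovery and false calls in the real VCaP comparisons may therefore differ from these. For ZBC-260 in Du145, 96 and 100 were recovered at 3 h with 17 false calls, and 94 and 99 at 24 h with 40 false calls.

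Alternatives were another scaling (median ratios), TPM as deposited, no filter, the replicate number as a block, a fit of only the groups compared, thalidomide as control and leaving out each library in turn. Added after the data were seen were a pseudocount of 0.1 (0.25 for single libraries), no variance trend, a correction for transcript length with and without the block, the fit of a single time with and without the block, and fits without the 24 h replicate 1 or 24 h thalidomide libraries. A count-based alternative could not be run on TPM. Genes with near-identical copies (histone genes, TRGJ1 and TRGJ2, STEAP1 and STEAP1B, UGT2B15 and UGT2B17) share reads, and their separate values are uncertain. Tables were handled with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and Biopython 1.88, and plots drawn with matplotlib 3.10.9.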

Results

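The series measured polyadenylated RNA in 3 human prostate cancer cell lines treated with compounds aimed at the BET family of proteins, chromatin readers that recruit the transcription machinery to acetylated histones. VCaP carries the fusion that drives ERG from the TMPRSS2 promoter, and 22Rv1 and Du145 do not. ERG measured 270 ± 102 TPM in VCaP DMSO libraries (SD, n = 4), 0.376 ± 0.276 in 22Rv1 (n = 2) and 0.443 ± 0.178 in Du145 (n = 2). Compounds known from the labels only by code names were the degraders ZBC-246 and ZBC-260, each at 10 nM, and the inhibitor ZBC-11 at 150 nM. Titles of VCaP and Du145 libraries read ZBX-246 where those of 22Rv1 read ZBC-246, and both were taken as the same compound. Thalidomide, a ligand of the ubiquitin ligase component cereblon, was given at 10 nM as a further control beside the DMSO vehicle. Cells were collected at 3 h and 24 h.

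VCaP had 2 libraries for each of DMSO, thalidomide, ZBC-246 and ZBC-11 at each time, 16 in all. Du145 and 22Rv1 had 1 library for each of the same 8 conditions, and a further Du145 set held 3 libraries of ZBC-260 and 3 of its control at each time. The values are TPM, which keep no depth, so the depth of each library is unknown. The 4 VCaP 24 h libraries of replicate 1 stood apart in signs of RNA quality. Ribosomal protein transcripts took 36.7% of TPM in DMSO, 49.0% in thalidomide, 35.2% in ZBC-246 and 28.3% in ZBC-11, against 24.0%, 24.7%, 24.1% and 20.7% in replicate 2. Long genes stood lower relative to short ones than in the median VCaP library, with log2 values of −1.197, −2.19, −1.09 and −0.52 in replicate 1 and between 0.21 and 0.58 in replicate 2. The comparisons at 24 h in VCaP rest on these libraries and their partners.

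**Figure D1:**
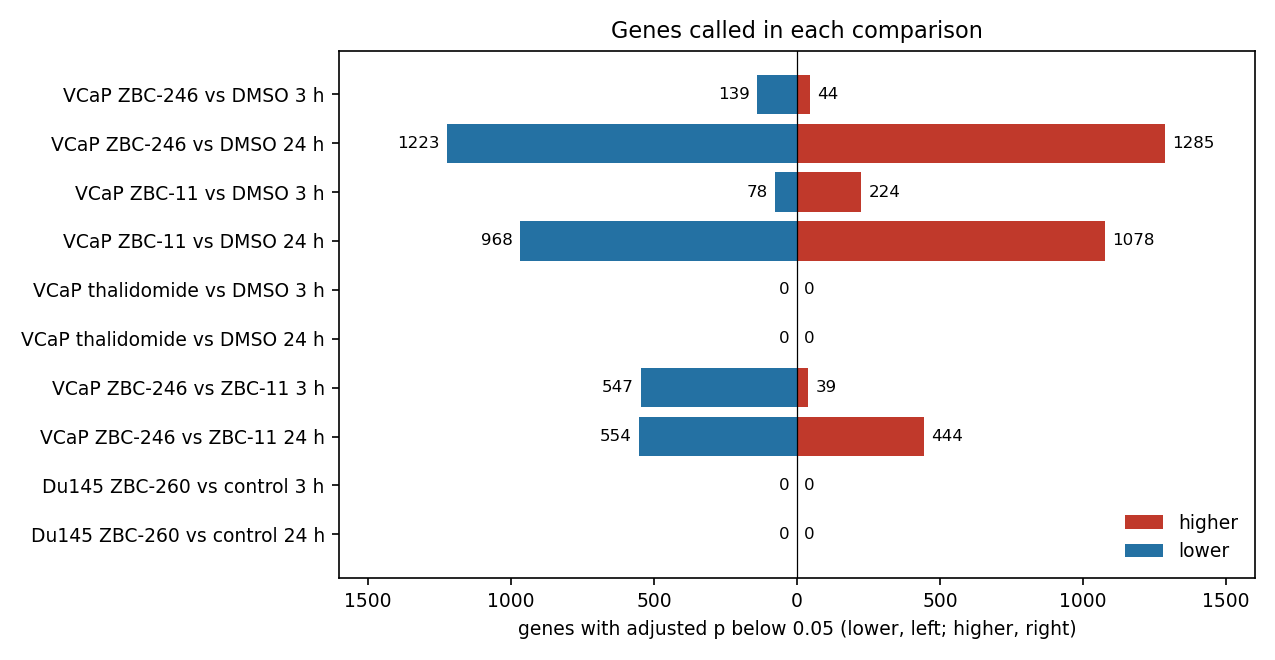
Number of genes with adjusted p below 0.05 in each replicated comparison, lower to the left and higher to the right (limma, all libraries of a set in 1 fit). Thalidomide in VCaP and ZBC-260 in Du145 gave 0 genes, and ZBC-246 at 3 h gave 139 lower and 44 higher.

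What the degrader did to VCaP transcripts within 3 h was asked by comparing ZBC-246 with DMSO (n = 2 each). MYC, the growth-promoting transcription factor whose dependence on BET proteins is well known, fell from 73.1 ± 3.72 to 4.09 ± 0.642 scaled TPM, a log2 change of −3.87 (SE 0.718, adjusted p = 0.0340). The gene (ENSG00000136997.17) lies on chromosome 8 at 127735434 to 127741434 (GRCh38, GENCODE 29). TRIB1, a pseudokinase that steers protein degradation, fell from 96.0 ± 19.0 to 10.7 ± 0.893 (log2 −3.04, SE 0.413, adjusted p = 0.0110). FOXA1, a pioneer factor of prostate epithelium, fell from 262 ± 36.0 to 81.5 ± 8.12 (log2 −1.67, SE 0.307, adjusted p = 0.0340). FAM83A, a gene tied to growth factor signalling, rose from 7.17 ± 0.514 to 151 ± 17.0 (log2 4.21, SE 0.557, adjusted p = 0.0110; ENSG00000147689.16, chromosome 8 at 123178960 to 123210079). In all, 183 of 15265 genes passed, 44 higher and 139 lower. Here and below, higher and lower are relative to the bulk of genes, which the scaling takes as unchanged.

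Other genes that fell at 3 h were PLK2, a kinase induced by stress (log2 −3.02), CCDC174 (−2.42), the homeobox gene IRX3 (−2.31), the lipoprotein receptor VLDLR (−2.13), RIPK4 (−2.10) and ZNF503 (−2.08). IRF1, an interferon-responsive transcription factor, changed by −1.71. MEPCE, which caps the 7SK RNA that holds the elongation kinase CDK9 inactive, changed by −1.56, from 36.1 to 11.8 TPM. The nuclease AEN fell by 1.40, the prostaglandin receptor PTGER4 by 1.34 and EED, a subunit of the Polycomb repressive complex, by 1.21. Among risers were the histone genes HIST1H4D (3.43), HIST2H2BF (2.88) and HIST2H2BE (1.39), IQCN (2.82), CCDC200 (3.25), the immediate early gene FOS (2.45), GADD45B (2.30) and NNMT (2.22). Histone genes share reads with near-identical copies, and their separate values are uncertain.

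HEXIM1, the 7SK-bound inhibitor of CDK9 and a common marker of BET inhibition (ENSG00000186834.3, chromosome 17 at 45148502 to 45152101), was not higher at 3 h of ZBC-246. It measured 16.2 ± 4.21 TPM against 28.95 ± 3.96 (log2 −0.82, SE 0.264, adjusted p = 0.2237). BRD2 and BRD3, genes of the BET family, gave log2 values of −0.48 and −0.14, neither of which passed. The same held for the androgen-induced genes KLK3 (0.32), TMPRSS2 (−0.63) and FKBP5 (0.04), for ERG (0.05), for the survival gene BCL2L1 (−0.48) and for the cell cycle inhibitor CDKN1A (0.94, adjusted p = 0.8099). These non-calls belong to the fit of both times without a replicate block. With a block and 3 h libraries alone, chosen after results were seen, limma called HEXIM1 (adjusted p = 0.0045), BRD2 (0.0145) and BCL2L1 (0.0141) lower. That fit called CDKN1A higher (0.0053).

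Of the fixed lists, 12 genes known from other studies to rise under BET inhibitors had a median of 0.82 (camera adjusted p = 2.90e-04), with 1 member past the test over all genes and 3 higher and 1 lower adjusted over the list alone. The call was lost at adjusted p = 0.2510 with an estimated correlation. A second list, of 14 genes known to fall under BET inhibitors, had 6 tested members. Its median was −0.87 with no camera call (adjusted p = 0.2613), and 1 member was lower on either adjustment. The 19 histone genes had a median of 0.74 (adjusted p = 4.69e-08, and adjusted p = 0.3293 with an estimated correlation), with 1 member higher, and 4 adjusted over the list alone. Medians of 0.50 for 35 ribosomal protein genes, 0.45 for 13 mitochondrially encoded genes and 0.36 for 12 lipid synthesis genes passed camera at 0.0044, 0.0086 and 0.0072 with 0 members past the limma test on either adjustment. Their values were adjusted p = 0.9233, adjusted p = 0.5547 and adjusted p = 0.3029 with an estimated correlation, and the lipid list did not pass without scaling (0.1469). Among 29 androgen-induced genes NNMT rose and PTGER4 fell, and the list gave a median of 0.08, a mean of −0.14 and no call (adjusted p = 0.8543). None of the 30 nucleolar MYC targets passed, with a median of 0.13 and a mean of −0.01.

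The count at 3 h fell when any 1 of the 4 libraries was left out (ZBC-246 replicate 1, ZBC-246 replicate 2, DMSO replicate 1 or DMSO replicate 2). Such a fit unbalances the replicate numbers, so a shift shared by same-numbered libraries enters the difference. A lost call then need not rest on the library left out. MYC then had adjusted p values of 0.1964, 0.2513, 0.3221 and 0.2385 while its log2 change stayed between −4.00 and −3.74 (over all 17 alternatives, adjusted p between 1.45e-04 and 0.3221), and of the 24 named genes that passed, only CCDC174 and RIPK4 passed in any of these 4 fits. With libraries of 3 h alone, 1212 genes passed, all 183 among them, and without scaling, which shifts the median of all genes by −0.24, 15 passed of which 66.7% were higher against 24% with it, and of the named genes FAM83A, CCDC200, NNMT and PLK2 did (MYC 0.2414).

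At 24 h the comparison of ZBC-246 with DMSO asked which changes were present after a day. KLK2, an androgen-driven prostate protease (ENSG00000167751.12, chromosome 19 at 50861568 to 50880567), fell from 6569 ± 3274 to 223 ± 7.91 TPM, a log2 change of −4.78 (SE 0.489, adjusted p = 1.66e-04, n = 2 each). CDKN1A, which stops the cell cycle, rose from 19.5 ± 13.2 to 434 ± 97.4 (log2 4.56, SE 0.646, adjusted p = 0.0011). GFPT2, an enzyme of hexosamine synthesis (ENSG00000131459.12, chromosome 5 at 180300690 to 180353387), rose from 0.955 ± 0.0779 to 297 ± 148 (log2 7.16, SE 0.370, adjusted p = 2.32e-06), and the neuronal gene ARC from 0.956 to 121 ± 8.10 (log2 5.96, adjusted p = 4.32e-07). MYC was at 7.89 ± 5.77 against 152 ± 87.8 (log2 −4.15, SE 0.718, adjusted p = 0.0035), and HEXIM1 rose from 21.8 ± 4.01 to 58.2 ± 13.6 (log2 1.37, SE 0.264, adjusted p = 0.0058). In all 2508 genes passed, 1285 higher and 1223 lower.

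Of the 12 markers known to rise under BET inhibitors, 11 rose and 1 fell, over all genes and adjusted over the list alone, with a median of 2.83 (camera adjusted p = 3.20e-10, and 0.0457 with an estimated correlation). SAT1, which breaks down polyamines, rose by 5.64 on the log2 scale to 6688 TPM, HIST1H2BD by 6.11 and SERPINI1 by 1.82. ZMYND8, a chromatin reader, was the member that fell (−2.32, adjusted p = 0.0042). The 6 tested genes known to fall under BET inhibitors had a median of 0.99 and no camera call (adjusted p = 0.7454). Of them 1 fell and 0 rose over all genes, and 1 fell and 3 rose adjusted over the list alone. Of 7 CDK inhibitors 6 rose, CDKN1C most of them (log2 6.80, 157 ± 121 TPM against 0.193), and the median was 1.76 (adjusted p = 1.63e-04, and 0.0457 with an estimated correlation). The 19 histone genes rose in 14 cases (14 adjusted over the list alone; median 2.36, adjusted p = 1.03e-11), with HIST2H2BE at log2 5.72. That call became adjusted p = 0.1584 with an estimated correlation.

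Immediate early genes rose in 13 of 21 cases and fell in 1, MYC, with 14 and 1 adjusted over the list alone. ATF3 (log2 5.93), CTGF (5.56), FOS (5.24) and EGR1 (3.90) were among them, and the median of 2.21 gave adjusted p = 5.28e-09, or adjusted p = 0.1124 with an estimated correlation. Of 20 genes of the ATF4 and endoplasmic reticulum stress response 10 rose and 1 fell (11 and 2 adjusted over the list alone; median 1.28), including DDIT4 (2.68) and the asparagine synthetase ASNS (2.52). Of 24 autophagy and lysosome genes 10 rose (12 adjusted over the list alone; median 0.90), including MAP1LC3B (2.21) and the protease CTSB (1.78). Camera gave adjusted p values of 2.72e-04 and 0.0027 for these lists, which became adjusted p = 0.4422 and adjusted p = 0.5014 with an estimated correlation. Further large rises were in PEG10, a gene derived from a retrotransposon (log2 6.39, 13380 ± 3337 TPM), and the matrix proteases MMP1 (68.8 ± 0.699 TPM against 0.0911) and MMP10 (log2 5.96). The heat shock co-chaperone DNAJB1 rose by 3.39, the survival gene MCL1 by 1.65 and the elongation kinase CDK9 by 1.18.

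Of 30 nucleolar MYC targets 17 fell and 0 rose at 24 h (23 and 1 adjusted over the list alone), among them RRS1 (−3.41), RCL1 (−2.30), TFB2M (−2.12) and DKC1 (−1.55), with a median of −1.48 (adjusted p = 4.69e-11, and adjusted p = 0.1584 with an estimated correlation). Of 29 androgen-induced genes 8 fell and 0 rose (8 and 1 adjusted over the list alone; median −0.42, adjusted p = 0.0032, and adjusted p = 0.1584 with an estimated correlation). KLK3, which encodes prostate-specific antigen (ENSG00000142515.14, chromosome 19 at 50854915 to 50860764), was at 4.36 ± 1.19 TPM against 66.8 ± 63.7 (log2 −3.26, SE 0.884, adjusted p = 0.0287). TMPRSS2 fell by 1.35 and the metalloreductase STEAP2 by 1.77.

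Of 8 genes known to be repressed by androgen, 3 fell and 1 rose (7 and 1 adjusted over the list alone; median −1.53, adjusted p = 0.0098, and adjusted p = 0.2873 with an estimated correlation). FOLH1, the prostate-specific membrane antigen, fell by 1.80, the steroid-conjugating UGT2B17 fell by 1.67 and its near-identical copy UGT2B15 was listed at 0 with ZBC-246, while cyclin D1 (CCND1) rose by 1.78. Among 14 genes tied to ERG, 6 fell and 1, MMP1, rose, over all genes and adjusted over the list alone (median −0.85, adjusted p = 0.0082, and adjusted p = 0.1584 with an estimated correlation). ERG fell from 215 to 61.5 ± 6.68 TPM (log2 −1.75, adjusted p = 0.0054). Of 12 lipid synthesis genes 6 fell (7 adjusted over the list alone), including ELOVL6 (−2.59), with a median of −0.83 (adjusted p = 0.0053, and adjusted p = 0.2215 with an estimated correlation). DNA replication genes fell in 2 of 30 cases (2 adjusted over the list alone), MCM3 (−1.48) and MCM6 (−1.37), with a median of −0.47 (adjusted p = 0.0356, and adjusted p = 0.8291 with an estimated correlation). Without scaling neither the ERG-linked list (0.0870) nor the replication list (0.0590) passed. Mitosis genes went the other way, with 5 of 29 higher, 13 adjusted over the list alone, CDC20 at 2.20, and a median of 1.33 (adjusted p = 2.72e-06, and adjusted p = 0.5867 with an estimated correlation). Large falls outside the lists were those of the T cell receptor gamma genes TRGV9 (−4.63) and TRGC1 (−4.45), LGI1 (−4.07) and the luminal factor SPDEF (−3.51). BRD2 and BRD3 had values of 0.75 and 0.83 with adjusted p of 0.3597 and 0.3272.

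With libraries of 24 h alone, where any shift shared by same-numbered libraries counts as spread, 357 genes passed, 356 of them shared with the 2508. Of 101 named genes 35 passed there, including GFPT2, CDKN1A, CDKN1C, ARC, ATF3, SAT1, KLK2, RRS1 and MMP1, while MYC (0.0699), HEXIM1 (0.0898), KLK3 (0.1583), ERG (0.0860) and TMPRSS2 (0.0832) did not. A fit without all 4 libraries of 24 h replicate 1 keeps 1 library per 24 h group, so its spread comes from 3 h alone. The median SD was 0.201 at 3 h and 0.472 at 24 h, so its count below does not measure a stronger response. Without DMSO replicate 1 or 2 the pooled fit called 1294 or 1262 genes, without ZBC-246 replicate 2 it called 1661, and without all 4 libraries of 24 h replicate 1 it called 4962. KLK3 then had adjusted p = 0.1993 without DMSO replicate 1, 0.1140 without ZBC-246 replicate 2 and 0.0522 without ZBC-246 replicate 1. HEXIM1 had 0.0624 without DMSO replicate 2, and TMPRSS2 had 0.0667, 0.0549 and 0.0584 without DMSO replicate 1, DMSO replicate 2 and ZBC-246 replicate 2. Without DMSO replicate 1, CDK9 had 0.0727, CCND1 0.0654, MCL1 0.0576, SPDEF 0.0819, MCM3 0.1258 and MCM6 0.1274. Without DMSO replicate 2, CDK9 had 0.1220 and FOLH1 0.0559, without ZBC-246 replicate 2 they had 0.1212 and 0.0512 and CCND1 had 0.0608, and without ZBC-246 replicate 1 MCM3 had 0.0686 and MCM6 0.0683. MYC and ERG passed without any 1 library, as did 58 of the 101. Over all 18 alternatives adjusted p ranged from 1.95e-04 to 0.1035 for MYC, from 7.89e-04 to 0.2646 for HEXIM1, from 6.79e-04 to 0.1993 for KLK3, from 0.0013 to 0.2352 for TMPRSS2 and from 4.37e-05 to 0.0762 for CDKN1A. Without scaling 1029 genes passed, 38.8% of them higher against 51.2% with it, as the median of all genes shifts by −0.10, and HEXIM1 then had adjusted p = 0.1916, ERG 0.1184, TMPRSS2 0.1340, CCND1 0.2419, CDK9 0.3887, MCL1 0.2516, FOLH1 0.0571, UGT2B17 0.0645, STEAP2 0.0781, DKC1 0.0560, CTSB 0.0528, MCM3 0.1314 and MCM6 0.1163.

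**Figure D2:**
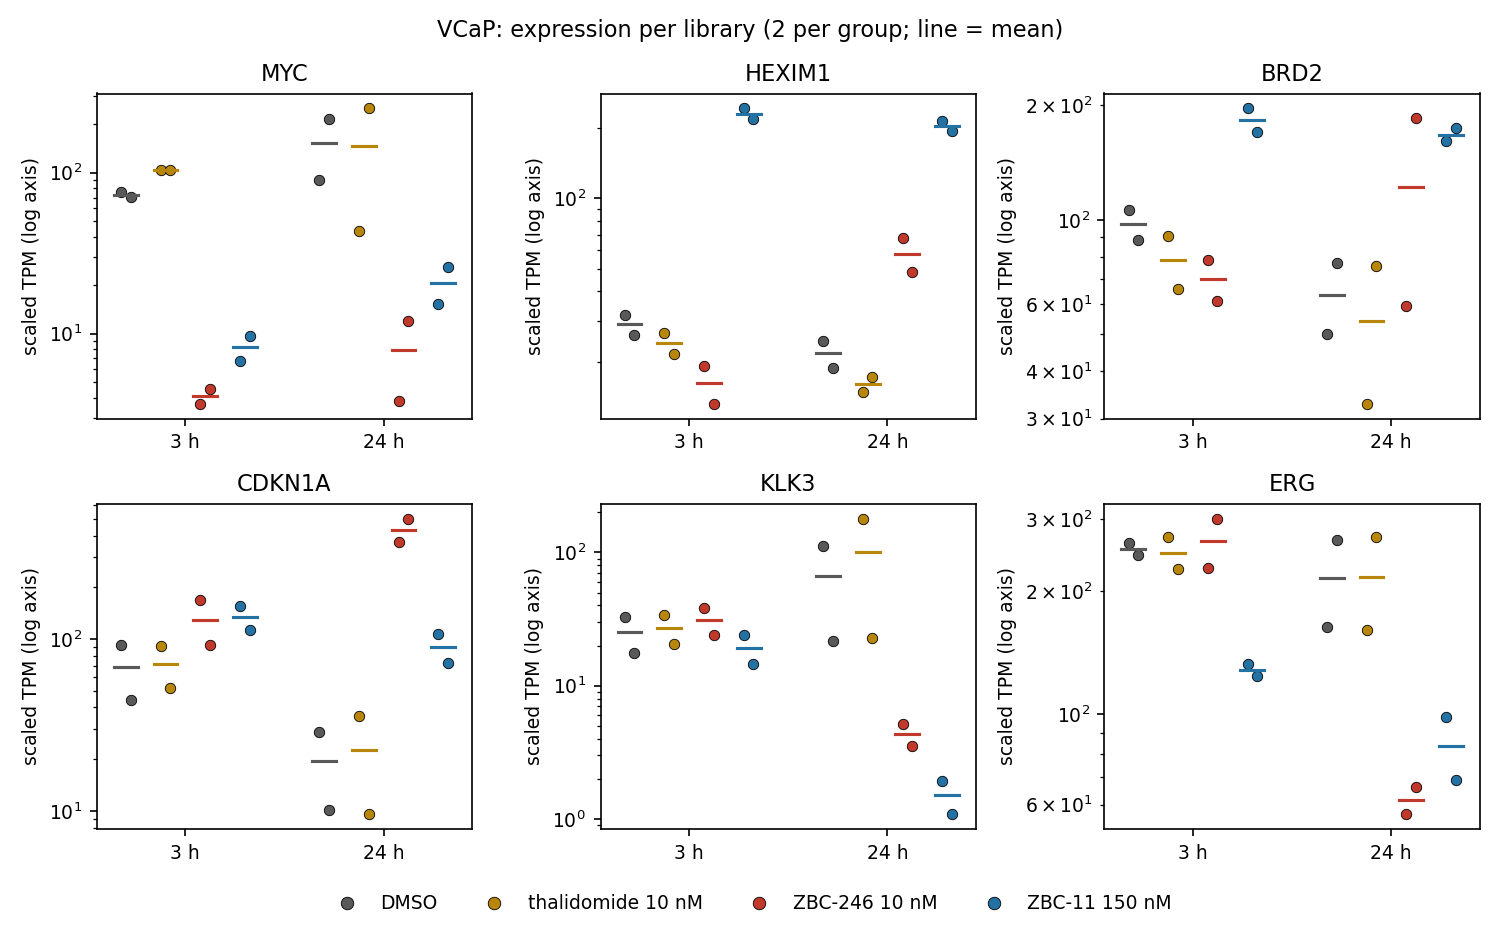
Scaled TPM (log axis) of 6 genes in each VCaP library by time and treatment, with points for libraries (2 per group) and lines for means. HEXIM1 sits at 231 TPM with ZBC-11 and 16.2 with ZBC-246 at 3 h, whereas MYC is low with both compounds.

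Whether the response to ZBC-246 differed between the times was tested as an interaction, the 24 h effect minus the 3 h effect. HEXIM1 differed by 2.19 on the log2 scale (SE 0.373, adjusted p = 0.0085), CDKN1A by 3.62 (SE 0.914, adjusted p = 0.0374) and ERG by −1.79 (SE 0.469, adjusted p = 0.0417). KLK2 differed by −5.12 (adjusted p = 0.0031), MMP1 by 6.17 and CTGF by 4.47. FOXA1 (2.06), MEPCE (1.68) and IRF1 (2.53), which fell at 3 h, also passed. MYC gave −0.28 (95% interval −2.51 to 1.95) and KLK3 −3.58 (adjusted p = 0.1053). In all 1217 genes differed, 728 upward and 489 downward. Of 139 genes lowered at 3 h, 15 were also called lower at 24 h (11.1 by independent lists), 66 (47.5%) had a negative value there, and their median was 0.09. Of 44 genes raised at 3 h, 37 were also called higher at 24 h (3.7 by independent lists). Across all genes the correlation between the times was 0.082.

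By list, 14 passed camera for the difference and 0 did with an estimated correlation, where the smallest were adjusted p = 0.0736 for the BET response markers (8 up, 1 down of 12; 11 and 1 adjusted over the list alone; median 2.28, adjusted p = 3.07e-07) and adjusted p = 0.0736 for CDK inhibitors (3 up of 7, 6 adjusted over the list alone; median 1.98, adjusted p = 4.57e-04). P-TEFb and 7SK genes, which control elongation, had 5 of 21 up (6 adjusted over the list alone; median 0.69, adjusted p = 0.0136, and adjusted p = 0.1072 with an estimated correlation). MYC targets had 8 of 30 down, or 15 adjusted over the list alone, with a median of −1.47 (adjusted p = 4.98e-10, and adjusted p = 0.1217 with an estimated correlation). Without all 24 h replicate 1 libraries the spread of the fit comes from 3 h libraries alone. Its count below therefore does not measure a larger difference. The count of 1217 went to 259 and 362 without 3 h DMSO replicate 1 and 2, 572 and 214 without 3 h ZBC-246 replicate 1 and 2, 573 and 450 without 24 h DMSO replicate 1 and 2, 2141 without 24 h ZBC-246 replicate 1, and 4548 without all 24 h replicate 1 libraries. HEXIM1 had adjusted p = 0.0514 without 3 h ZBC-246 replicate 2 and 0.0577 without 3 h DMSO replicate 1. Of the 8 fits that leave out 1 library, ERG kept its call in 2, those without 24 h ZBC-246 replicate 2 and without 24 h DMSO replicate 1, and CDKN1A in 2, those without 24 h ZBC-246 replicate 1 and without 24 h DMSO replicate 1. Their highest values were 0.1652 for ERG without 3 h ZBC-246 replicate 2 and 0.1647 for CDKN1A without 3 h DMSO replicate 1. FOXA1 kept its call in 2 of the 8, MEPCE in 4 and IRF1 and CTGF in 5, with highest values of 0.1029, 0.1037, 0.0816 and 0.0692. Over 19 alternatives HEXIM1 ranged from 9.72e-04 to 0.1446, ERG from 0.0035 to 0.4834 and CDKN1A from 0.0027 to 0.1647.

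The inhibitor ZBC-11 was compared with DMSO to describe BET inhibition without degradation. At 3 h HEXIM1 rose from 28.95 ± 3.96 to 231 ± 17.7 TPM (log2 2.96, SE 0.264, adjusted p = 5.11e-04, n = 2 each). SERPINI1, a serine protease inhibitor, rose from 1.74 to 17.0 ± 3.62 (log2 2.70, SE 0.319, adjusted p = 0.0018), HIST2H2BE from 3.81 to 54.1 ± 3.58 (3.52, adjusted p = 1.79e-04) and GFPT2 from 2.27 to 68.6 ± 9.52 (4.41, adjusted p = 4.42e-04). TMPRSS2 fell from 129 ± 31.2 to 47.6 ± 13.5 (log2 −1.42, SE 0.309, adjusted p = 0.0426). MYC was at 8.23 ± 2.07 against 73.1 ± 3.72, a log2 value of −3.02 (SE 0.718) that missed the threshold at adjusted p = 0.0636 and passed with 3 h libraries alone (6.00e-04). In all 302 genes passed, 224 higher and 78 lower.

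Of the 12 BET response markers 7 rose at 3 h of ZBC-11, and 11 rose and 1 fell adjusted over the list alone (median 2.52, adjusted p = 1.30e-16, and 0.0093 with an estimated correlation). The 6 tested genes known to fall under BET inhibitors had a median of 0.02 and no camera call (adjusted p = 0.4664). Of them 1 was lower adjusted over the list alone. Of 21 immediate early genes 8 rose (13 rose and 1 fell adjusted over the list alone; median 1.28), among them ATF3 (3.10), FOS (2.34), IER5 (2.32) and DUSP5 (1.85). Histone genes rose in 6 of 19 cases (9 adjusted over the list alone; median 1.08), HIST1H2BC by 3.66. The heat shock genes DNAJB1 (1.46) and BAG3 (1.39) rose, 2 of 11 on either adjustment, with a list median of 0.52. Camera gave adjusted p values of 5.62e-12, 3.73e-13 and 6.60e-04 for these lists, or adjusted p = 0.0740, adjusted p = 0.2288 and adjusted p = 0.2288 with an estimated correlation. Other rises were those of PEG10 (3.53), the germ cell gene TEX14 (3.52), the CDK inhibitor CDKN2B (1.91) and the sterol genes INSIG1 (1.86) and IDI1 (1.37). Falls included ZBED1 (−3.32), the collagen gene COL4A2 (−2.13), VLDLR (−1.86), the androgen-induced PMEPA1 (−1.85, 103 against 372 TPM) and the adhesion gene ICAM1 (−1.22). ERG (−0.98, adjusted p = 0.2099), BRD2 (0.91, adjusted p = 0.5768), BCL2L1 (−1.23, adjusted p = 0.1705), CDKN1A (1.03) and KLK3 (−0.34) did not pass. With 3 h libraries alone ERG (0.0097), BRD2 (0.0346) and BCL2L1 (0.0275) did.

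The count at 3 h of ZBC-11 was 44 and 68 without ZBC-11 replicate 1 and 2, and 77 and 63 without DMSO replicate 1 and 2. HEXIM1, SERPINI1, GFPT2, HIST2H2BE, HIST1H2BC, IER5, DUSP5, TEX14 and HIST2H4A, 9 of 34 named genes, passed in all 4 of these fits. TMPRSS2 had adjusted p = 0.1065, 0.3349, 0.3385 and 0.1189 in the order of the 4 libraries above, ZBED1 0.0713, 0.0865, 0.0811 and 0.0788, and PEG10 0.0691 without ZBC-11 replicate 1 and 0.0539 without DMSO replicate 2. The other genes named here lost their calls without each of the 4. Over 17 alternatives adjusted p ranged from 1.26e-04 to 0.4122 for MYC and from 0.0039 to 0.4136 for TMPRSS2. With 3 h libraries alone 1669 genes passed, including all 302, and without scaling (a shift of −0.10) 92 did, of which 91.3% were higher against 74.2% with it, among them HEXIM1, SERPINI1, GFPT2, PEG10 and ZBED1 but not TMPRSS2 (0.4136) or FOS (0.0896).

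At 24 h of ZBC-11 HEXIM1 was at 205 ± 14.4 TPM against 21.8 ± 4.01 (log2 3.19, SE 0.264, adjusted p = 9.05e-05), and KLK2 at 130 ± 39.5 against 6569 ± 3274 (−5.59, SE 0.489, adjusted p = 1.18e-04). PEG10 reached 11550 ± 3351 against 162 ± 59.3 (6.17, adjusted p = 7.57e-05), GFPT2 rose by 5.83 and CDKN1C by 4.65. ACSL5, a fatty acid ligase, fell from 32.3 ± 0.330 to 0.614 ± 0.0604 (−4.37, SE 0.268, adjusted p = 2.59e-05). MYC was at 20.5 ± 7.55 against 152 ± 87.8 (−2.75, SE 0.718, adjusted p = 0.0278). In all 2046 genes passed, 1078 higher and 968 lower.

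The BET response markers rose in 9 of 12 cases and ZMYND8 fell (−2.25, adjusted p = 0.0057), or 11 and 1 adjusted over the list alone, with a median of 2.84 (adjusted p = 8.82e-10, and 0.0296 with an estimated correlation). The 6 tested genes known to fall under BET inhibitors had a median of 0.81 and no camera call (adjusted p = 0.8428). Of them 2 were lower on either adjustment. Genes tied to ERG fell in 8 of 14 cases on either adjustment, with PLA1A (−3.65), ARHGDIB (−3.30) and CRISP3 (−2.26) beside ERG itself (−1.33), and a median of −1.08 (adjusted p = 6.73e-06, and 0.0296 with an estimated correlation). MYC targets fell in 16 of 30 cases and rose in 1 (25 and 1 adjusted over the list alone; median −1.37), for example TFB2M (−2.12) and CAD (−1.36). DNA replication genes fell in 15 of 30 cases (19 adjusted over the list alone; median −1.65), for example MCM5 (−2.49), MCM2 (−2.33) and MCM3 (−2.15), and DNA repair genes in 6 of 25 (8 adjusted over the list alone; median −0.91), for example RAD54L (−1.85) and PALB2 (−1.43). These 3 calls (adjusted p = 1.70e-12, 7.53e-11 and 9.66e-05) became adjusted p = 0.1506, adjusted p = 0.4560 and adjusted p = 0.4806 with an estimated correlation.

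Rises at 24 h of ZBC-11 included 4 of 7 CDK inhibitors (5 adjusted over the list alone; median 2.08), with CDKN1A at 2.29 (adjusted p = 0.0390), 9 of 21 immediate early genes with 1 fall (11 and 1 adjusted over the list alone; median 1.03), 8 of 19 histone genes (11 adjusted over the list alone; median 1.27) and 8 of 24 autophagy genes with 1 fall (10 and 1 adjusted over the list alone; median 0.81). Lipid synthesis genes fell in 5 of 12 cases on either adjustment (median −0.77), ELOVL6 by 2.56. Camera gave 0.0012, 4.56e-05, 6.40e-06, 0.0012 and 0.0034 for these 5 lists in turn, which became adjusted p = 0.0685, adjusted p = 0.2651, adjusted p = 0.4806, adjusted p = 0.5513 and adjusted p = 0.2651 with an estimated correlation. Among androgen-induced genes 6 fell, with KLK3 at −4.36 (1.51 against 66.8 ± 63.7 TPM), TRPM8 at −2.90 and TMPRSS2 at −1.71, and 2 rose (8 and 3 adjusted over the list alone). The list of 29 did not pass (median −0.38, adjusted p = 0.1613). Further falls were those of DDC (−4.91), SPDEF (−4.62), TSPAN1 (−4.33), the nucleotide kinase NME1 (−4.07), the matrix protein TNC (−4.06) and the death receptor FAS (−3.33). CSRP2 (3.62), the protease inhibitor SERPINE2 (3.81) and CCND1 (2.11) rose, and BRD2 (1.42, adjusted p = 0.0916), BRD3 (0.25) and FKBP5 (−0.54) did not pass.

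With 24 h libraries alone, under the same limit as for ZBC-246, 251 genes passed, 250 of them shared, and 24 of 93 named genes, including HEXIM1, SERPINI1, GFPT2, PEG10, CDKN1C, KLK2, DDC, ACSL5, PLA1A and ARHGDIB, while MYC (0.1796), KLK3 (0.0986), ERG (0.1652), TMPRSS2 (0.0569) and CDKN1A (0.1746) did not. In the pooled fit the count was 782 and 760 without ZBC-11 replicate 1 and 2, 843 and 1151 without DMSO replicate 1 and 2, and 873 without scaling. MYC then had adjusted p of 0.1729, 0.0749 and 0.1535 without ZBC-11 replicate 1, ZBC-11 replicate 2 and DMSO replicate 2, ERG 0.0560, 0.1504 and 0.1252 and CDKN1A 0.2017, 0.1187 and 0.2472 without the same libraries. KLK3 had 0.0681 and 0.0791 without ZBC-11 replicate 2 and DMSO replicate 1, and TMPRSS2 0.0514 and TRPM8 0.0586 without ZBC-11 replicate 2. Without ZBC-11 replicate 1, FAS had 0.0637, MCM2 and MCM5 0.0562, RAD54L 0.0637, NME1 0.0512 and TNC 0.1547. Without ZBC-11 replicate 2, NME1 had 0.1009 and TNC 0.0792, without DMSO replicate 1 NME1 had 0.1120 and RAD54L 0.0722, and without DMSO replicate 2 TNC had 0.1526. Of the 93, 51 passed without any 1 library. Without scaling MYC had 0.2312, ERG 0.4117, TMPRSS2 0.1504, CCND1 0.0844, FAS 0.0900, TNC 0.1285, TRPM8 0.0822, CAD 0.2732, CRISP3 0.0534, PALB2 0.0959, RAD54L 0.0820, MCM2 0.0945, MCM3 0.0822 and MCM5 0.0893. Over 18 alternatives adjusted p ranged from 0.0012 to 0.2312 for MYC, 0.0029 to 0.4117 for ERG, 1.54e-04 to 0.0986 for KLK3, 0.0028 to 0.2472 for CDKN1A and 9.07e-06 to 0.0359 for HEXIM1.

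**Figure D3:**
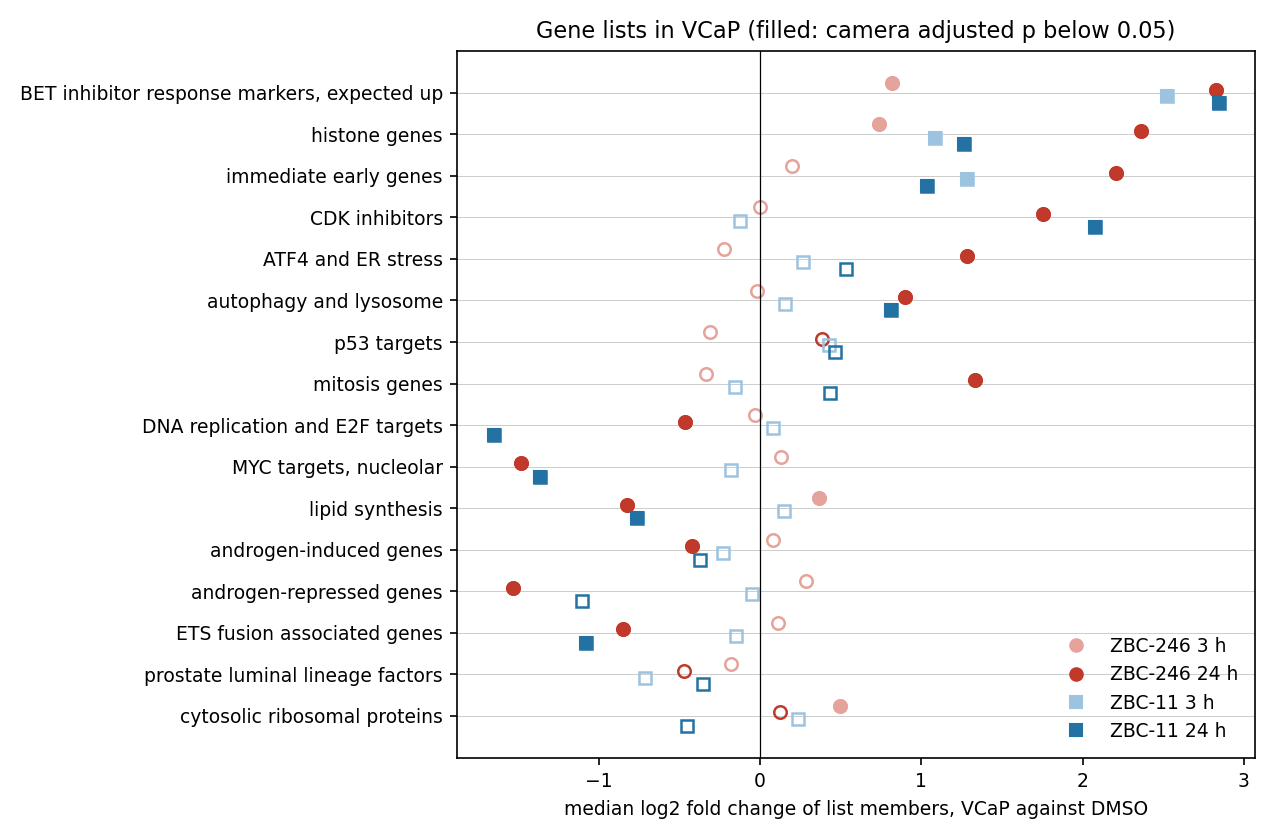
Median log2 fold change against DMSO of the members of 16 fixed gene lists in VCaP, for ZBC-246 (circles) and ZBC-11 (squares) at 3 h (pale) and 24 h (dark), filled where camera's adjusted p with the preset correlation was below 0.05. The BET response markers stand at 0.82 and 2.83 for ZBC-246 and 2.52 and 2.84 for ZBC-11.

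Degrader and inhibitor were set against each other directly, at doses that differed (10 nM and 150 nM). At 3 h HEXIM1 was lower with ZBC-246, at 16.2 ± 4.21 against 231 ± 17.7 TPM (log2 −3.77, SE 0.264, adjusted p = 1.43e-04, n = 2 each). Its partner in the 7SK complex, MEPCE, was at 11.8 ± 3.30 against 76.4 ± 4.70 (−2.62, SE 0.256, adjusted p = 5.89e-04). SERPINI1 (−2.13), the single-stranded DNA binding gene NABP1 (−3.39) and TEX14 (−3.15) were also lower with the degrader, as was FOXA1 at 81.5 against 222 TPM (−1.43, adjusted p = 0.0269). NNMT (2.27) and ZMYND8 (1.79) were higher. Of 586 genes that differed 547 were lower with ZBC-246 and 39 higher. The intervals of the difference for genes that did not pass were −2.42 to 0.73 for MYC (4.09 against 8.23 TPM), −2.50 to −0.28 for BRD2, 0.30 to 1.76 for ERG, −1.28 to 2.61 for KLK3 and −1.51 to 1.33 for CDKN1A.

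By list at 3 h, 6 of 12 BET response markers were lower with ZBC-246 and 1 higher on either adjustment (median −1.69, adjusted p = 3.48e-07, and adjusted p = 0.1247 with an estimated correlation). Lower too were 4 of 21 immediate early genes (7 adjusted over the list alone; median −0.82), such as IER5 (−1.68) and DUSP5 (−2.13), and 4 of 19 histone genes (6 adjusted over the list alone; median −0.57), such as HIST1H2BC (−2.55). The p53 targets SESN2 (−2.03), BTG2 (−1.42) and PLK3 (−1.18) were among 5 of 20 (7 adjusted over the list alone; median −0.43), the stress gene DDIT3 (−2.49) among 3 of 20 in the ATF4 list (4 adjusted over the list alone; median −0.29), and BAG3 (−2.21) was 1 of 11 heat shock genes (3 adjusted over the list alone; median −0.43). Camera gave adjusted p values of 5.01e-07, 0.0042, 0.0136, 0.0236 and 0.0358, or adjusted p = 0.1904, adjusted p = 0.7033, adjusted p = 0.1540, adjusted p = 0.7295 and adjusted p = 0.4549 with an estimated correlation. MYC targets had a median of 0.28 with 0 of 30 members past the limma test on either adjustment (adjusted p = 0.0150, and adjusted p = 0.7033 with an estimated correlation). The count of 586 became 220 and 127 without ZBC-246 replicate 1 and 2, 95 and 123 without ZBC-11 replicate 1 and 2, and 177 without scaling, where FOXA1 had 0.4678, ZMYND8 0.6309, BTG2 0.3266, PLK3 0.1008 and BAG3 0.0520. HEXIM1, MEPCE, NABP1, TEX14, IER5, DUSP5, BAG3 and HIST1H2BC passed without any 1 of these libraries and with scaling, and all 41 named genes that differed passed with 3 h libraries alone. SERPINI1 had adjusted p = 0.0690 without ZBC-246 replicate 2 and 0.0994 without ZBC-11 replicate 1. FOXA1 had 0.1142, 0.2355, 0.3742 and 0.1494 without ZBC-246 replicate 1, ZBC-246 replicate 2, ZBC-11 replicate 1 and ZBC-11 replicate 2. In the same order ZMYND8 had 0.1541, 0.2714, 0.2788 and 0.1409, DDIT3 0.0810, 0.1372, 0.1784 and 0.1373, and PLK3 0.0741, 0.1356, 0.1787 and 0.1350. Without the last 3 of these libraries SESN2 had 0.0924, 0.0862 and 0.0965 and BTG2 0.3653, 0.3338 and 0.2378, while NNMT had 0.0609, 0.0723 and 0.0552 without the libraries other than ZBC-246 replicate 2. With 3 h libraries alone MYC (0.0218), BRD2 (0.0058) and ERG (0.0058) passed, and over 16 alternatives MYC ranged from 0.0059 to 1.0000.

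At 24 h HEXIM1 was still lower with ZBC-246 (58.2 ± 13.6 against 205 ± 14.4 TPM, log2 −1.82, SE 0.264, adjusted p = 0.0034). The prostate surface antigens STEAP1 (94.99 against 1152 TPM, −3.79, adjusted p = 0.0014) and FOLH1 (−2.84) were lower with it as well, with STEAP1B (−3.42, a near-identical copy), CFAP69 (−3.50) and TRGV9 (−3.53). MMP10 (176 ± 10.1 against 1.06 TPM, log2 6.46, adjusted p = 1.23e-05), MMP1 (5.57), ARC (5.50), CTGF (3.58) and PLA1A (2.64) were higher. In all 998 genes differed, 444 higher and 554 lower. MYC (−2.98 to 0.18), ERG (−1.14 to 0.32), KLK3 (−0.85 to 3.04), SERPINI1 (−1.37 to 0.04) and CDKN1A (0.85 to 3.69, adjusted p = 0.0625) did not pass, these being 95% intervals of the log2 difference.

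Several lists stood higher with ZBC-246 than with ZBC-11 at 24 h, all losing the call with an estimated correlation. DNA replication genes had 6 of 30 members higher (7 adjusted over the list alone; median 1.10), for example MCM5 (1.80) and RRM2 (1.52), where ZBC-11 had lowered more of them than ZBC-246. Histone genes had 3 of 19 (12 adjusted over the list alone; median 1.17), immediate early genes 8 of 21 on either adjustment (median 0.67), with FOS at 2.36, ATF4 genes 6 of 20 (9 adjusted over the list alone; median 0.64) and mitosis genes 0 of 29 on either adjustment (median 0.89). Their camera adjusted p values were 3.21e-07, 2.51e-07, 1.36e-04, 2.11e-04 and 1.78e-04, or adjusted p = 0.5875, adjusted p = 0.5875, adjusted p = 0.5112, adjusted p = 0.5875 and adjusted p = 0.7057 with an estimated correlation. The ERG-linked list (3 of 14 higher on either adjustment; median 0.30, adjusted p = 0.0166) and NF-kB genes (2 of 12, 4 adjusted over the list alone; median 0.50, adjusted p = 0.0441) both gave adjusted p = 0.4374 with an estimated correlation. With 24 h libraries alone, shared shifts again counting as spread, 29 genes passed, 28 of them shared, and of 46 named genes tested there ARC, MMP1, MMP10 and STEAP1B did, HEXIM1 having 0.1094 (6.53e-04 to 0.2874 over 17 alternatives). The count of 998 was 2058 and 367 without ZBC-246 replicate 1 and 2, 210 and 152 without ZBC-11 replicate 1 and 2, and 465 without scaling, 30.5% of them higher against 44.5% with it (a shift of −0.29), where MCM5 had 0.3545, RRM2 0.3737, ATF3 0.0976, FOS 0.0596 and TRGV9 0.0530. HEXIM1, STEAP1, FOLH1, PLA1A and HIST2H2BE beside those 4 passed without any 1 library. CTGF had adjusted p = 0.0729 and FOS 0.0727 without ZBC-11 replicate 2, CFAP69 0.0721 and 0.0987 without ZBC-246 replicate 2 and ZBC-11 replicate 1, TRGV9 0.0515 and 0.0790 without ZBC-246 replicate 2 and ZBC-11 replicate 2, RRM2 0.1041 and 0.1507 without ZBC-246 replicate 2 and ZBC-11 replicate 1, and MCM5 0.1321, 0.2369 and 0.1446 without ZBC-246 replicate 2, ZBC-11 replicate 1 and ZBC-11 replicate 2.

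Agreement of the compounds was measured with no shared control by setting ZBC-246 against thalidomide beside ZBC-11 against DMSO. Fold changes then correlated across genes at 0.338 at 3 h and 0.659 at 24 h. At 3 h 25 genes were called higher and 18 lower in both, against 0.7 and 0.7 for independent lists, and at 24 h 456 and 700, against 98.1 and 88.7. With the DMSO libraries shared the correlations were 0.394 and 0.658, and simulated unchanged groups gave 0.5 and 0.501. With equal noise in all groups a shared control sets such a correlation by construction, so 0.394 is not agreement below chance. The covariances of 0.118 and 0.532 exceeded the simulated ones by 0.0686 and 0.313. The simulated noise took in any shift shared by same-numbered libraries, which cancels between these groups, so the simulated covariances may be too large. Of 224 genes raised by ZBC-11 at 3 h, 131 (58.5%) had a positive value with ZBC-246, with a median of 0.06. Of 78 lowered ones 75 (96.2%) had a negative value, with a median of −0.79.

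Thalidomide at 10 nM served to show what the ligase ligand does by itself. By limma 0 genes passed at 3 h and 0 at 24 h in VCaP, with 58 and 90 genes at an unadjusted p below 0.05 where chance gives 763. With counts this far under chance the p-values of this fit ran high. It counts any shift shared by same-numbered libraries as spread, though such a shift cancels between these groups. The 0 calls therefore do not show that thalidomide changed no gene. Within replicate 1 and within replicate 2, the thalidomide differences correlated across genes at −0.118 at 3 h and 0.113 at 24 h. MYC gave log2 values of 0.50 (95% interval −1.08 to 2.08) and −0.40 (−1.98 to 1.18), and HEXIM1 −0.26 and −0.41. Without 3 h DMSO replicate 2 the count was 1, and without 24 h thalidomide replicate 2 it was 5. Lists gave 0 calls at 3 h. At 24 h ribosomal protein genes (median 0.71, adjusted p = 2.61e-08), proteasome genes (0.37, adjusted p = 0.0025) and MYC targets (0.25, adjusted p = 0.0228) passed camera with 0 members past limma on either adjustment. All 3 had adjusted p = 0.9746 with an estimated correlation, and without scaling, which shifts the median of all genes by −0.36, the proteasome and MYC lists had 0.5405 and 0.9217. Replicate 1 of this group held 49.0% ribosomal protein TPM.

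Whether the other lines shared the VCaP response was read from single libraries, which have no replicate check and no test. In 22Rv1 MYC measured 4.54 TPM with ZBC-246 at 3 h against 126 with DMSO (log2 ratio −4.51) and 6.60 against 110 at 24 h (−3.86), and with ZBC-11 its ratios were −3.26 and −3.42. HEXIM1 had ratios of −0.60 and 0.92 with ZBC-246 at 3 h and 24 h and of 2.33 and 1.84 with ZBC-11. CDKN1A was at 421 against 74.1 TPM with ZBC-246 at 24 h (2.49) but at 70.5 with ZBC-11 (−0.07), unlike in VCaP. At 24 h KLK3 had ratios of −2.55 with ZBC-246 and −2.09 with ZBC-11, and TMPRSS2 of −1.71 with each. Of genes called in VCaP with ZBC-246 at 3 h, 32 of 34 raised and 124 of 127 lowered ones (94.1% and 97.6%) had the same sign in 22Rv1, and at 24 h 88.8% and 92.9% did. For ZBC-11 these shares were 96.5% and 95.2% at 3 h and 85.1% and 89.8% at 24 h. Correlations across genes with VCaP were 0.584 and 0.634 for ZBC-246 at 3 h and 24 h, and 0.561 and 0.499 for ZBC-11. The BET response markers had a median of 2.96 with ZBC-246 at 24 h, higher in 12 of 12, while 30 of 30 DNA replication genes (median −1.34) and 28 of 30 MYC targets (−0.97) were lower.

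**Figure D4:**
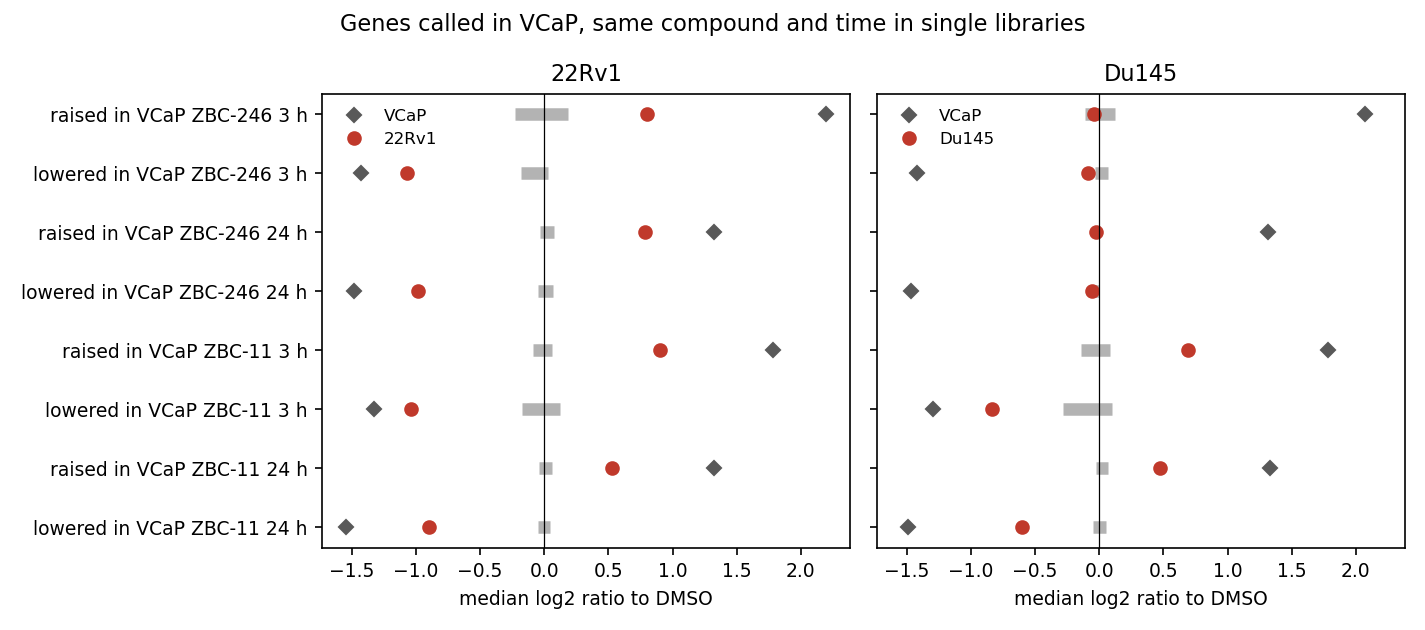
Median log2 ratio to DMSO of the genes called in VCaP, in VCaP (diamonds) and in single libraries of 22Rv1 and Du145 (circles) given the same compound for the same time, with grey bars for the middle 95% of 10000 random lists matched on expression. In Du145 the medians lie at 0.69 and −0.84 for genes raised and lowered by ZBC-11 at 3 h, and at −0.04 and −0.09 for those of ZBC-246.

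In the single Du145 library of ZBC-246 at 3 h 171 genes were over 2-fold higher and 167 lower, beside 153 and 153 with thalidomide, and 847 and 955 with ZBC-11. MYC had ratios of −0.36 and 0.33 at 3 h and 24 h of ZBC-246, −0.70 and 0.54 with ZBC-11 and −0.25 and 0.48 with thalidomide. HEXIM1 had −0.18 and −0.49 with ZBC-246. Of genes raised and lowered in VCaP by ZBC-246, 46.2% and 65.6% had the same sign in Du145 at 3 h and 44.4% and 58% at 24 h, with correlations of 0.107 and 0.064. The lowered genes lay below random lists, at percentile 0 (median −0.09) at 3 h and 0.41 (−0.05) at 24 h, where 49.8% and 52.3% of all genes had a negative ratio, and the raised ones lay at percentiles 19.9 and 5.62. Such percentiles also arose in control libraries: genes raised in VCaP at 24 h lay at percentile 0 (median −0.06) with thalidomide in Du145 and at percentile 100 (median 0.045) with thalidomide in 22Rv1. For ZBC-11 86.3% and 82.5% had the same sign at 3 h and 81.6% and 86.9% at 24 h, with correlations of 0.370 and 0.465. HEXIM1 was then higher, with ratios of 2.33 and 1.39, as was SERPINI1 with 1.61 and 2.04. FOSL1, a Jun partner known to depend on BET proteins in cells without high MYC dependence, was at 23.5 against 107 TPM at 24 h of ZBC-11 (−2.14), with ratios of 0.16 for ZBC-246 and 0.13 for thalidomide. The ZBC-11 library of 3 h had long genes lower relative to short ones than the median Du145 library (log2 −1.05).

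Du145 received the other degrader, ZBC-260, in 3 libraries per group. By limma 0 of 15698 genes passed at 3 h, 0 at 24 h and 0 for the difference between times, with 1266, 669 and 1131 genes at an unadjusted p below 0.05, where chance gives 785. MYC was at 69.0 ± 2.25 against 64.7 ± 8.02 TPM at 3 h (log2 0.10, 95% interval −0.17 to 0.36) and 39.6 ± 0.525 against 39.5 ± 7.13 at 24 h (0.02, −0.24 to 0.28). HEXIM1 had log2 values of −0.24 (−0.48 to 0) and −0.11 (−0.35 to 0.13), SERPINI1 of 0.14 (−0.22 to 0.50) and 0.35 (−0.01 to 0.71), and FOSL1 of 0.20 (−0.04 to 0.46) and −0.36 (−0.61 to −0.12, adjusted p = 0.9942). BRD2 gave 0.18 and −0.01, and CDKN1A 0.15 and −0.05. Leaving out ZBC-260 replicate 3 or control replicate 3 at 24 h gave 2 and 1 genes.

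The Du145 lists moved by small amounts. At 3 h ribosomal protein (median 0.10, adjusted p = 1.81e-10), mitosis (0.18, adjusted p = 2.24e-10), mitochondrially encoded (0.13, adjusted p = 7.06e-10) and cholesterol synthesis genes (0.11, adjusted p = 3.74e-06) passed camera, with 0 members called over all genes and 0, 3, 10 and 1 adjusted over the list alone. With an estimated correlation these gave adjusted p = 0.5075, adjusted p = 0.4209, adjusted p = 0.4209 and adjusted p = 0.3249. The histone, replication, proteasome and lipid lists passed with medians of 0.16, 0.12, 0.06 and 0.13 and had 0 members called on either adjustment (adjusted p = 0.5915, adjusted p = 0.6026, adjusted p = 0.4209 and adjusted p = 0.4209 with an estimated correlation). At 24 h 6 lists passed with medians between −0.15 (cell line identity genes, adjusted p = 0.0285) and −0.04 (ribosomal proteins, adjusted p = 0.0208), all at adjusted p = 0.7057 with an estimated correlation. The BET response markers did not pass at 3 h (median 0.11, adjusted p = 0.4644) or 24 h (0.15, adjusted p = 0.0546). CRBN, which encodes the ligase component that thalidomide binds, was at 20.3 ± 4.91 TPM in the controls of this set (n = 6), 19.9 ± 0.0536 in the Du145 DMSO libraries (n = 2), 35.8 ± 11.1 in VCaP (n = 4) and 37.2 ± 0.876 in 22Rv1 (n = 2).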

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

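The tests on scaling, transcript length, replicate 1, spread and response genes below were chosen only after results were seen, while the splits of Du145 libraries and the CRBN ratio were written down before. A difference between the 3 h and 24 h effects of ZBC-246 in VCaP brought out 4 values, each from an interaction test of 2 libraries per group. The test passed for 1217 genes, for HEXIM1 with a log2 difference of 2.19, for ERG with −1.79 and for CDKN1A with 3.62. Part of the HEXIM1 difference comes from 3 h, where its value was −0.82 (adjusted p = 0.2237), and part from 24 h, where it was 1.37.

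Genes lower with ZBC-246 than with ZBC-11 at 3 h in VCaP made up 547 of 586 differences, HEXIM1 and MEPCE among them. With TPM left unscaled the median log2 difference of these genes was −1.651, against −1.52 with scaling, but leaving the scaling out lowers the median of all genes (0.03 to −0.08), so this says nothing against uneven scaling. The number called lower was 170 unscaled and 489 with median-ratio scaling, and a part for scaling stays open. A bias by transcript length is argued against, since 90.5% were still called lower with the length trend removed. The design sets a degrader at 10 nM against an inhibitor at 150 nM, and the contribution of dose to the difference stays open.

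The 2508 genes called for ZBC-246 at 24 h rest in part on replicate 1 libraries with high ribosomal protein shares and few long transcripts. If loss of long transcripts made the calls, removing the length trend would end most of them, but 2262 (90.2%) were still called. If replicate 1 alone set their direction, replicate 2 would often not share it. Of 3306 genes over 2-fold apart within replicate 1, called or not, 2979 (90.1%) had the same sign within replicate 2. Over all genes 74% did. For those genes this argues against a direction set by replicate 1 alone. Whether replicate 1 changed the size or the number of the calls cannot be read from signs and stays open. Calls that ended with the length trend removed stay open.

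No gene passed for ZBC-260 in Du145 by limma, with 1266 genes at an unadjusted p below 0.05 at 3 h and 669 at 24 h. Spread that hides changes of the size seen in VCaP is argued against by the genes called there at 24 h. Their median change in Du145, signed by the VCaP direction, was 0.024 (2156 genes) against 1.39 in VCaP. The median SE of a gene at 24 h in Du145 was 0.149. An interval of 0.017 to 0.032 came from resampling these genes, which are not independent, and does not measure spread between libraries. That BET response genes move with no BET compound in Du145 is argued against by the 12 response markers. They were fixed from other studies, but all 12 were also called in VCaP with ZBC-246 at 24 h (11 higher, 1 lower). The median of these markers was 1.30 at 3 h and 1.089 at 24 h of ZBC-11, each in 1 library against its own DMSO and at percentile 100 of random lists, beside −0.13 and −0.26 with thalidomide. The 3 h ZBC-11 library had long genes lower relative to short ones (log2 −1.05). CRBN transcript in Du145 was 0.53 of the higher of the other lines. This ratio of means met the bound of 0.5 set beforehand against a low level, and was not under the lower bound set for it. Single libraries fell under 0.5, so a part for cereblon level stays open, and its protein was not analysed here. The 10 splits of the 6 libraries at each time are too few for a test: the real split gave 0 genes at both times, all 10 of 10 splits gave as many, and the highest other gave 3 at 3 h and 221 at 24 h. Genes at an unadjusted p below 0.05 numbered 1266 for the real split at 3 h and at most 717 for the others, and 669 for the real split at 24 h and up to 1901 for the others.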

How the results depend on the processing

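The correction for transcript length, the fits of 1 time with and without a block, of a pseudocount of 0.1, with no variance trend and without the 24 h replicate 1 or 24 h thalidomide libraries were tests chosen only after results were seen. Counts of genes are given in the order ZBC-246 at 3 h (183 as reported), ZBC-246 at 24 h (2508), ZBC-11 at 3 h (302), ZBC-11 at 24 h (2046), ZBC-246 against ZBC-11 at 3 h (586) and 24 h (998), and the difference between times (1217). With no scaling they were 15, 1029, 92, 873, 177, 465 and 156. With only the groups compared in the fit they were 407, 12, 1072, 387, 1784, 0 and 75, the 0 coming from limma, and 3 for thalidomide at 3 h and 1 for ZBC-260 at 3 h. With libraries of the same time only, the first 6 were 1212, 357, 1669, 251, 2247 and 29, and ZBC-260 at 3 h gave 1. These fits differ in spread, residual degrees of freedom and genes tested at once. Length correction gave 603 and 3111 for ZBC-11 at 3 h and 24 h, 891 and 1677 between compounds and 2330 between times. With no filter thalidomide gave 2 and 1 at 3 h and 24 h and ZBC-260 5, 7 and 6, the last between times. Without the 24 h thalidomide libraries thalidomide at 3 h gave 2, and with no variance trend ZBC-260 gave 3, 1 and 3. Leaving out libraries, where a lone library is assumed to vary like the other groups, gave 2 to 10, 1262 to 4962, 44 to 77, 760 to 2652, 95 to 220, 152 to 3379 and 214 to 4548, thalidomide 0 to 1 and 0 to 5, and ZBC-260 0 to 0, 0 to 2 and 0 to 1. In each case the cause was not tested. The highest counts at 24 h and between times for the degrader and the inhibitor came from fits without all 24 h replicate 1 libraries. Those fits took their spread from 3 h libraries alone.

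VCaP libraries share only the replicate numbers 1 and 2, which no label explains. Deviations of libraries of the same number and time correlated at 0.40 to 0.907 (median 0.671), and across times at −0.209 to 0.581. With 2 replicates the deviations of a group mirror each other, so both numbers give the same values. Leaving out 1 library unbalances the replicate numbers, so a shared shift then enters the difference between groups. Calls lost in those fits need not rest on the library left out. With a replicate block the 7 counts were 470, 3810, 650, 3216, 1097, 1905 and 2479, and 138 gene and 11 list results gained a call. Of non-calls in the report, MYC (adjusted p = 0.0128) and BCL2L1 (0.0047) with ZBC-11 at 3 h, CDKN1A between compounds at 24 h (0.0092) and KLK3 between times (0.0163) passed with the block. With block and length correction the counts were 672, 5153, 1131, 4417, 1587, 3090 and 3757. With the block and libraries of the same time only, at 3 residual degrees of freedom, the first 6 were 3161, 3261, 3717, 2687, 4701 and 978, and ZBC-260 at 3 h gave 1. At 24 h 99 of the 101 named genes with ZBC-246, 88 of the 93 with ZBC-11 and 37 of 46 between compounds then passed. MYC had adjusted p = 0.0012 and 0.0052 at 24 h of ZBC-246 and ZBC-11, HEXIM1 0.0111 and 0.0015, KLK3 0.0116 and 0.0056, ERG 0.0109 and 0.0285, TMPRSS2 0.0108 and 0.0058 and CDKN1A 0.0022 and 0.0241. In this fit 269 gene results gained a call. At 3 h of ZBC-246 they included lower HEXIM1 (0.0045), BRD2 (0.0145) and BCL2L1 (0.0141) and higher CDKN1A (0.0053), at 3 h of ZBC-11 CDKN1A (0.0031) and KLK3 (0.0366), and between compounds at 3 h MYC (0.0059), BRD2 (2.84e-04), ERG (0.0025) and KLK3 (0.0030). At 24 h BRD2 with ZBC-11 (0.0401) and CDKN1A between compounds (0.0430) passed.

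Median-ratio scaling and a pseudocount of 0.1 kept each of these 7 counts within 1.5 times. No named gene or list reversed its direction while called. With thalidomide as the control, 1 of the 302 and 1 of the 2046 genes called for ZBC-11 had the opposite sign. Of gene results, median-ratio scaling left 1760 on the same side of the threshold, with 14 weaker and 4 stronger, and unscaled TPM 1669, with 235 weaker and 12 stronger. Leaving out libraries left 9080, with 878 weaker and 161 stronger. Of list results, an estimated correlation left 350 and made 79 weaker. DESeq2 was not run, as it takes counts. Depth is unknown, so no limit for genes listed at 0 is given.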

Other observations

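The test of a small Du145 response below was chosen only after results were seen. In the single Du145 library of ZBC-11 at 24 h, 18 of 20 NF-kB genes (median −1.50), 20 of 22 interferon genes (−1.08) and 29 of 29 mitosis genes (−1.07) were lower than in DMSO. In 22Rv1 with ZBC-246 at 24 h histone genes had a median of 2.90 and p53 targets of 1.12.

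Genes lowered by ZBC-246 in VCaP at 3 h were lower in Du145 with ZBC-260 at 3 h by a small amount (median −0.12 over 129 genes), and the 27 raised ones were higher (0.13). A small response to ZBC-260 in the VCaP direction was tested with camera, where the lowered genes gave adjusted p = 1.41e-05 with the preset correlation and adjusted p = 0.0636 with an estimated correlation. The same genes had a median of −0.04 in the single Du145 thalidomide library, at percentile 3.95 of random lists, and of −0.09 in the single Du145 ZBC-246 library, at percentile 0. Percentile 0 was also reached with thalidomide in Du145 at 24 h, by genes raised in VCaP by ZBC-246 at 24 h (median −0.06). Whether such a response exists stays open.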
